A study of Noccaea caerulescens and Thlaspi montanum with 10 samples.

How the data were processed

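Leaves of 3 Noccaea plants had been sampled at their field sites, from 2 separate individuals of each, and stabilised in RNAlater. Per the labels' protocols, total RNA was extracted with the RNeasy Plant Mini kit and treated with DNase, and strand-specific mRNA libraries (TruSeq Stranded mRNA) were made from 1 µg of it and sequenced as Illumina paired ends. Per the series' design text, a reference transcriptome was assembled de novo from root and leaf reads of hydroponically grown plants, and the firmiensis transcriptome served as the common reference for all 3 plants. The hydroponic plants had received 37.5 µM NiCl2 and 20 µM Fe-HBED, an iron chelate, for 7 weeks, and their 4 libraries of 10 in the series were not analysed here. The labels date the firmiensis leaves to July and the leaves of the other two plants to June of 2014. Month therefore coincides with firmiensis, which alone was collected in July, and site with plant. Viviez replicate 2 carries run label number 4 and the other field libraries 5, and what that number stands for is not given in the sources used here.

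The deposited values are raw read counts per transcript, per the file headers, 1 value per library for 41843 transcripts named only by a contig number. The assembler, aligner, counting tool, their versions and any filter are not given in the sources used here. Values were whole numbers with a different total in each library, and replicates had not been pooled. Empty cells were found for 2 transcripts, which were left out, and 1688 of the remaining 41841 had 0 reads in every library. There were 0 columns of samples from another series. The deposited counts hold an excess of even numbers among the lowest counts: the ratio of transcripts with 2 reads to transcripts with 1 read was 1.475 ± 0.0636 in firmiensis, 1.34 ± 0.099 in Viviez and 1.09 ± 0.0849 in N. montana (SD, n = 2). Among counts of 21 to 200, even numbers made up 52.3% (exact 95% interval 51.3 to 53.3) and 52.6% (51.5 to 53.6) in firmiensis and 52% (50.9 to 53) and 53.1% (52 to 54.2) in Viviez. In N. montana they made up 50.3% (49.2 to 51.3) and 50.8% (49.8 to 51.8), with no detectable excess. Both mates of a pair may have been counted in some cases, more in firmiensis and Viviez than in N. montana, which was not tested. Reads may therefore not be independent molecules, and the intervals and limits given here cover counting error only. No sequences, gene names or gene models were used here. Lists of metal transport, chelation, iron response and other genes had been fixed before the data were examined, but 0 of them could be matched to numbered contigs and no test of a gene list was made.

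Counts were tested in R 4.3.3 with edgeR 4.0.16. Transcripts were kept by filterByExpr with its minimum count of 10, which left 32989 transcripts holding 99.96% of reads. Libraries were scaled by TMM factors, and the quasi-likelihood fit (glmQLFit, glmQLFTest, installed default) used all 6 libraries in 1 model with a coefficient per plant and 3 residual degrees of freedom. The common biological coefficient of variation was 39.5% and the prior degrees of freedom were 3.18. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Levels are normalised CPM (edgeR cpm, with TMM scaling), as mean ± SD over 2 individuals, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Where a group had 0 reads, a fold is given as a lower bound from raw library totals against 3 reads over that group. For presence and absence, unscaled CPM of at least 1 in both libraries was set against at most 3 reads over both libraries of another plant.

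The rule for naming transcripts was set before the data were examined. For IDs without gene names it takes, in each comparison, the 2 with the largest positive and the 2 with the largest negative log2 fold change. They had to pass the threshold, reach a mean CPM of at least 5 over both groups, and show no overlap between the groups' libraries. For the transcripts higher or lower in firmiensis than in both others it takes the 2 with the smallest larger adjusted p. The transcript of highest mean level in each plant, and contig_23505, were singled out after their values were seen.

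The procedure was tested on simulated counts with a single mean per transcript over all libraries, the depths of these libraries and the fitted spread of each transcript. In each comparison 200 transcripts were changed. For firmiensis against Viviez, with 31907 transcripts tested, 28.4% of 4-fold, 76.1% of 16-fold and 80.3% of 64-fold changes were recovered, and 8.89% of calls were false. For firmiensis against N. montana, with 31915 transcripts tested, 20.9%, 70.1% and 81.8% were recovered and 7.26% of calls were false. For Viviez against N. montana, with 31871 tested, 23.9%, 62.7% and 86.4% were recovered and 6.5% of calls were false. No changed transcript was called in the wrong direction. In the real comparisons far more transcripts passed the threshold, 14.2 to 36.6% of those tested. These rates therefore describe the simulated setting and need not hold for the lists reported here.

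Alternatives set before the data were examined were RLE and upper quartile scaling, TMM factors from transcripts with at least 10 reads in every library, and DESeq2 1.42.0 and limma 3.58.1 (voom) in place of edgeR. Others were no filter on low counts, at least 1 CPM in every library, a minimum log2 fold change of 1 with or without its own test (glmTreat), fits of only the 4 libraries compared, a replicate block, and leaving out each library in turn. Where that left a plant with 1 library, that library was assumed to vary like the other groups. Such a fit has fewer residual degrees of freedom and filters transcripts anew. Fewer calls for that plant can therefore follow whichever of its libraries is left out. Presence was also defined at 5 CPM and absence at 0 reads. The newer quasi-likelihood fit of edgeR, a fit without the 20 most abundant transcripts, and presence and absence without each library were added after seeing the data. Replicate numbers do not pair these plants, which were separate individuals at separate sites. Figures were drawn with matplotlib 3.10.9.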

Results

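Leaf transcripts were compared among 3 plants of the genus Noccaea (Brassicaceae) growing at field sites in southern France. Noccaea caerulescens subsp. firmiensis (firmiensis) was labelled a nickel hyperaccumulator, a plant that stores nickel in its shoots at levels that would poison most other plants. A population of N. caerulescens from Viviez (Viviez) and the related species N. montana were labelled as plants that do not accumulate nickel. The comparisons ask which leaf transcripts separate the hyperaccumulator from a relative of its own species and from a relative of another species. Each plant was represented by leaves of 2 separate individuals, and each individual gave 1 polyA RNA library, so that the spread within a group is the spread between plants. The hydroponic libraries of the series, 4 in number, were not analysed here.

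Between 59476715 and 68439128 reads per library were counted on 41841 transcripts assembled from firmiensis. The libraries of replicates 1 and 2 held 59476715 and 60576935 reads in firmiensis, 63042462 and 59687511 in Viviez, and 68439128 and 68408974 in N. montana. Reads were found on 36182 ± 658 transcripts in firmiensis, 34756 ± 617 in Viviez and 37000 ± 22 in N. montana (SD, n = 2). At these depths 3 reads correspond to 0.0438 to 0.0504 CPM in a library, where CPM are read counts scaled to library size. The transcripts carry numbers and no gene names, so no transcript can be tied here to a metal transporter or to any other function, and each is given by its number. Reads shared between near-identical transcripts were not resolved, which leaves the level of any single transcript uncertain to that extent.

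Leaves of the same plant resembled each other more than leaves of different plants did. The root mean square difference of log2 CPM over the 32989 transcripts tested lay between 0.817 and 1.12 for the 3 pairs of individuals of the same plant. It rose to between 1.81 and 1.92 for firmiensis against Viviez, between 2.09 and 2.21 for firmiensis against N. montana, and between 2.26 and 2.33 for Viviez against N. montana. No 2 libraries of a plant were copies of each other, with a chi-square per degree of freedom of 158 in firmiensis, 101 in Viviez and 179 in N. montana, and each was counted as a replicate. In all, 15911 transcripts (48.2%) differed in at least 1 of the 3 comparisons and 17078 (51.8%) passed the threshold in none.

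**Figure D1:**
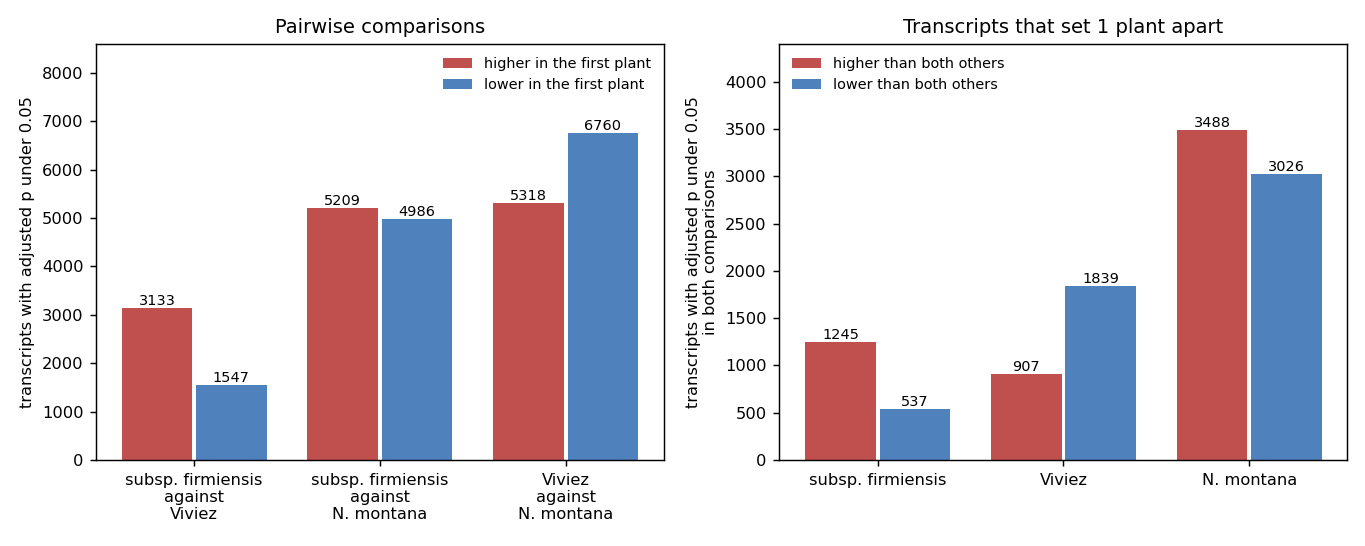
Bars give numbers of transcripts with an adjusted p under 0.05, for each pair of plants (left) and for transcripts past the threshold in both comparisons of a plant with the same sign (right). Of the transcripts that differed between firmiensis and Viviez, 3133 were higher and 1547 lower in firmiensis, and N. montana had the tallest bars on the right, 3488 higher and 3026 lower than in both others.

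The hyperaccumulator and the Viviez plants, members of the same species, differed in 4680 of 32989 leaf transcripts (14.2%), of which 3133 were higher and 1547 lower in firmiensis. The transcripts higher in firmiensis made up 11.2 ± 0.41% of its reads and 3.24 ± 0.28% of those of Viviez (SD, n = 2). The transcripts higher in Viviez made up 13.5 ± 2.4% of its reads and 2.7 ± 0.4% of those of firmiensis. Among them contig_1579 alone held 5.3 ± 2.57% of the Viviez reads. Over all tested transcripts, the median absolute log2 fold change lay between 0.43 and 1.18 by class of mean CPM. Past the threshold, which favours large differences, it was 3.33 among the higher and 2.5 among the lower transcripts. It was 3.2 and 2.49 with transcripts at 0 reads in a group set at their lower bound. With such bounds, 775 transcripts were at least 32-fold higher and 225 at least 32-fold lower in firmiensis. Contig_38941 stood at 405 ± 165 CPM in firmiensis and had no read in Viviez, at least 15001-fold higher against the limit of 3 reads over the group (edgeR adjusted p = 0.00374). It was also read in N. montana, at 132 ± 79.2 CPM. Contig_15663 stood at 133 ± 22.8 CPM in firmiensis, at least 4969-fold higher than in Viviez, where it had no read (edgeR adjusted p = 0.00768). In the other direction, contig_25404 had no read in firmiensis and 20.8 ± 5.84 CPM in Viviez, at least 802-fold lower in firmiensis (edgeR adjusted p = 0.0147). Leaving out either Viviez library ended that call, with edgeR adjusted p of 0.0668 and 0.0693, the latter the highest over its 13 alternatives, which began at 1.76e-11. Contig_10677 had no read in firmiensis and 17.8 ± 8.54 CPM in Viviez, at least 690-fold lower in firmiensis (edgeR adjusted p = 0.00557), or at least 436-fold without Viviez replicate 1. The quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment gave these calls, and 63.5% of all tested transcripts had no overlap between the groups, where chance gives 33.3%. The number of differing transcripts fell when any library was left out, most without a Viviez library, whichever of the 2 it was. A plant is then left with 1 library, which alone can lower the number. With DESeq2 8261 transcripts differed, and 1993 when tested against a log2 fold change of 1. Over transcripts with at least 1 CPM in every library, 1971 differed.

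The hyperaccumulator differed from N. montana in 10195 transcripts (30.9%), with near-equal numbers in each direction, 5209 higher and 4986 lower in firmiensis. The transcripts higher in firmiensis made up 34.7 ± 2.2% of its reads and 12.3 ± 1.5% of those of N. montana (SD, n = 2). The transcripts higher in N. montana made up 22.1 ± 2% of its reads and 4.3 ± 0.59% of those of firmiensis. The median absolute log2 fold change was 2.55 among the higher and 2.66 among the lower transcripts, or 2.54 and 2.66 with transcripts at 0 reads in a group set at their bound. With such bounds, 809 transcripts were at least 32-fold higher and 704 at least 32-fold lower in firmiensis. Contig_2505 stood at 63.0 ± 18.7 CPM in firmiensis and had no read in N. montana, at least 2694-fold higher (edgeR adjusted p = 0.000975), and it was read in Viviez at 26.1 ± 1.06 CPM. Contig_13750 stood at 48.9 ± 8.02 CPM in firmiensis, at least 2079-fold higher than in N. montana (edgeR adjusted p = 0.00181), and had no read in either other plant. Contig_16363 was read only in N. montana among the 6 libraries, where it stood at 101.5 CPM in replicate 1 and 6.856 CPM in replicate 2, at least 2412-fold lower in firmiensis (edgeR adjusted p = 0.0242). Contig_40138 had no read in firmiensis and stood at 85.64 CPM in N. montana replicate 1 and 4.776 CPM in replicate 2, at least 2011-fold lower in firmiensis (edgeR adjusted p = 0.0165). Both bounds rest on N. montana replicate 1, without which they were at least 320-fold for contig_16363 and at least 223-fold for contig_40138, against 4503 and 3798 without replicate 2. Over 13 alternatives the adjusted p ranged from 0.00716 to 0.0711 for contig_16363, which missed the threshold with limma voom and without either firmiensis library. It ranged from 0.000157 to 0.0856 for contig_40138, which missed it with limma voom and without firmiensis replicate 1. The groups did not overlap in 70.1% of tested transcripts, where chance gives 33.3%. The number of differing transcripts fell to 5936 without firmiensis replicate 1, 5319 without N. montana replicate 1 and 5941 without N. montana replicate 2. It was 5115 when tested against a log2 fold change of 1 and 5197 over transcripts with at least 1 CPM in every library.

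The plants without nickel accumulation differed from each other in 12078 transcripts (36.6%), of which 5318 were higher and 6760 lower in Viviez. The transcripts higher in Viviez made up 38.8 ± 1.5% of its reads and 11.2 ± 0.041% of those of N. montana (SD, n = 2). The transcripts higher in N. montana made up 27.9 ± 1.4% of its reads and 5.33 ± 0.19% of those of Viviez. The median absolute log2 fold change was 2.25 among the transcripts higher and 3.09 among those lower in Viviez, or 2.24 and 3.04 with transcripts at 0 reads in a group set at their bound. With such bounds, 660 transcripts were at least 32-fold higher and 1323 at least 32-fold lower in Viviez. Contig_20449 stood at 96.1 ± 43.1 CPM in Viviez and had no read in N. montana, at least 4113-fold higher (edgeR adjusted p = 0.00184), and firmiensis had 0.146 ± 0.151 CPM. Contig_1124 stood at 79.6 ± 5.03 CPM in Viviez and had no read in N. montana, at least 3455-fold higher (edgeR adjusted p = 0.0436). The same transcript stood at 60.25 CPM in firmiensis replicate 1 and had 3 reads in firmiensis replicate 2. Its call was lost in 6 of 13 alternatives, over which the edgeR, DESeq2 or limma adjusted p ranged from 4.17e-05 to 0.122, among them leaving out any single Viviez or N. montana library. Contig_38941 had no read in Viviez and was at least 6224-fold lower there than in N. montana (edgeR adjusted p = 0.00157), or at least 3463-fold without N. montana replicate 2. Contig_1613 had no read in Viviez and 56.0 ± 3.47 CPM in N. montana, at least 2602-fold lower in Viviez (edgeR adjusted p = 0.0016). The groups did not overlap in 75.3% of tested transcripts, where chance gives 33.3%. The number of differing transcripts fell to 5174 without Viviez replicate 1, 5250 without Viviez replicate 2, 7563 without N. montana replicate 1 and 7625 without N. montana replicate 2. Without a Viviez library it lay below that of firmiensis against N. montana. That fit compared 1 Viviez library, but 2 of firmiensis, with N. montana, so this order does not rank the pairs. The root mean square log2 difference between single libraries was 2.26 to 2.33 for Viviez and 2.09 to 2.21 for firmiensis against N. montana. Tested against a log2 fold change of 1, 6737 transcripts differed. Over transcripts with at least 1 CPM in every library, 6069 did.

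The transcripts that separate the hyperaccumulator from both other plants were 1245 that were higher in firmiensis than in each and 537 that were lower than in each. The 1245 higher transcripts made up 5.16 ± 0.26% of the reads of firmiensis, 1.43 ± 0.098% of those of Viviez and 1.48 ± 0.19% of those of N. montana (SD, n = 2). The 537 lower transcripts made up 0.288 ± 0.032%, 1.19 ± 0.029% and 1.5 ± 0.094% of reads in the same order. Of the higher transcripts, 876 did not pass the threshold between the other two plants, as did 382 of the lower ones. With bounds for transcripts at 0 reads, 612 were at least 8-fold higher in firmiensis than in both others and 194 at least 8-fold lower. Contig_1368 stood at 26.1 ± 0.939 CPM in firmiensis, 0.222 ± 0.00804 CPM in Viviez and 0.0643 ± 0.0023 CPM in N. montana. Its log2 fold change was 6.87 ± 0.31 (SE, edgeR adjusted p = 0.0018) against Viviez and 8.62 ± 0.34 (SE, edgeR adjusted p = 0.000796) against N. montana. Contig_19860 stood at 33.3 ± 1.97 CPM in firmiensis. It was at least 1254-fold higher than in Viviez, where it had no read (edgeR adjusted p = 0.00225), and higher by 7.67 ± 0.39 on the log2 scale than in N. montana (SE, edgeR adjusted p = 0.00144). Contig_5248 stood at 0.123 ± 0.0639 CPM in firmiensis, 674 ± 30.8 CPM in Viviez and 4.14 ± 0.357 CPM in N. montana. Its log2 fold change was -12.37 ± 0.45 (SE, edgeR adjusted p = 0.0018) against Viviez and -5.03 ± 0.37 (SE, edgeR adjusted p = 0.00166) against N. montana. Its firmiensis level rests on 4 and 10 reads. The log2 fold changes were -11.96 and -4.6 without firmiensis replicate 1, and -13.05 and -5.68 without firmiensis replicate 2. Contig_907 stood at 0.314 ± 0.0315 CPM in firmiensis, 41.5 ± 3.37 CPM in Viviez and 17.7 ± 3.6 CPM in N. montana. Its log2 fold change was -7.04 ± 0.31 (SE, edgeR adjusted p = 0.0018) against Viviez and -5.81 ± 0.3 (SE, edgeR adjusted p = 0.000826) against N. montana.

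Both comparisons use the same firmiensis libraries, which alone can produce shared calls and a correlation. In 20 simulations of 3 unchanged groups, at most 1 transcript passed in both comparisons with the same sign, against 1782 observed, but a simulation gave at most 6 calls over all 3 comparisons, which leaves little room for an overlap. Independent lists of the observed lengths would share 495 higher and 234 lower transcripts. The covariance of the log2 fold changes across transcripts was 1.82, against 0.24 in the simulations, a difference of 1.58, and their correlation was 0.323, against 0.504. Computed from mean log2 CPM, the covariance was 2, of which the measured spread between the firmiensis individuals gives 0.632, a difference of 1.37. The simulated 0.24 lies below this 0.632, though it was computed differently. The simulations may thus understate the firmiensis spread, so 1.58 may be too large and 0.504 is not a matched reference. With 2 firmiensis libraries these could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared libraries. The same count was 2746 for Viviez (907 higher, 1839 lower) and 6514 for N. montana (3488 higher, 3026 lower). Neither was recomputed without each library, and the firmiensis against Viviez calls that enter the Viviez count fell strongly without a Viviez library. Leaving out any library moved the 1245 higher transcripts by over 1.5 times: to 611 and 818 without firmiensis replicate 1 and 2, to 299 and 223 without Viviez replicate 1 and 2, and to 749 and 808 without N. montana replicate 1 and 2. The 537 lower transcripts fell to 302 without firmiensis replicate 1, 122 and 112 without Viviez replicate 1 and 2, and 313 without N. montana replicate 1.

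**Figure D2:**
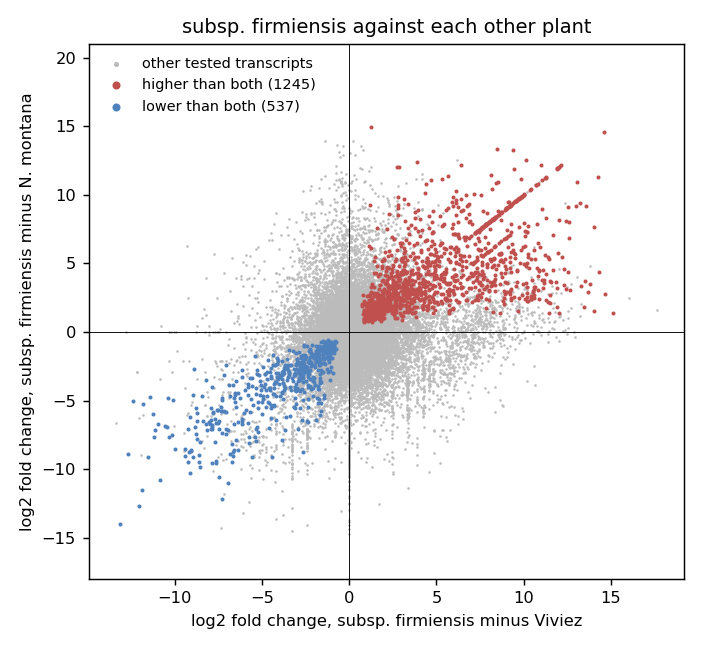
Each point is a tested transcript, with the log2 fold change of firmiensis minus Viviez on the horizontal axis and of firmiensis minus N. montana on the vertical axis. Coloured points passed the threshold in both comparisons with the same sign, 1245 higher (upper right) and 537 lower (lower left) in firmiensis; fitted values of transcripts at 0 reads in a group depend on the prior count, which draws the straight lines of points.

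**Figure D3:**
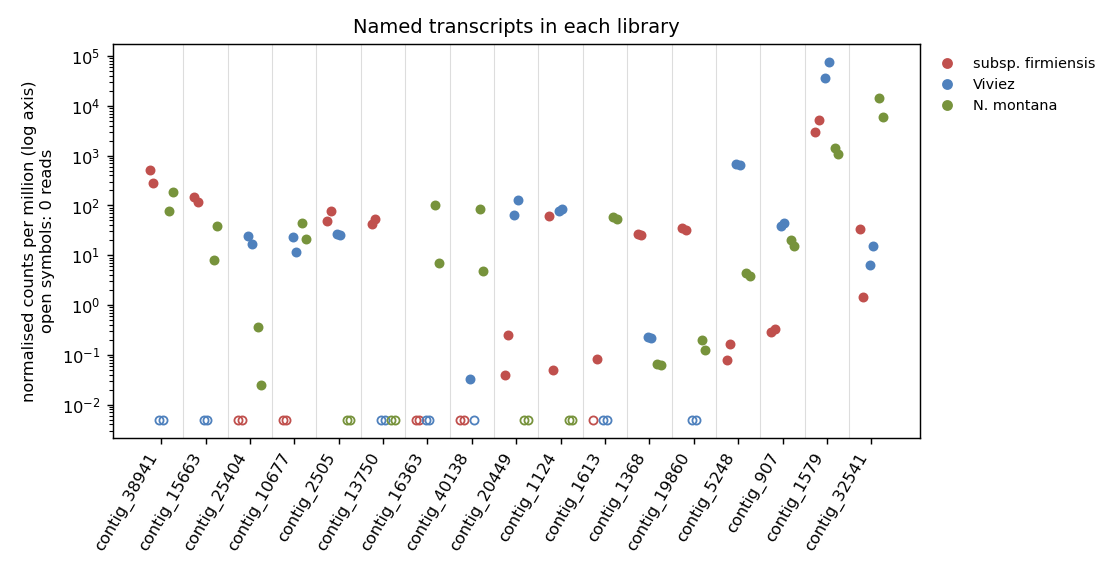
Each symbol is the normalised CPM of 1 library on a log axis, for the named transcripts and the transcripts of highest mean level in Viviez (contig_1579) and N. montana (contig_32541); open symbols mark 0 reads. The 2 individuals of a plant lie close together for contig_1368 and contig_907, and far apart for contig_16363, contig_40138 and, in firmiensis, contig_1124 and contig_32541.

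Some transcripts were read in both individuals of 1 plant and not detected in another plant. Between the 2 N. caerulescens plants the numbers were uneven: 347 transcripts were present in firmiensis, at 1 CPM or more in both libraries, and had at most 3 reads over both Viviez libraries, and 76 were present in Viviez and not detected in firmiensis. Between firmiensis and N. montana, 188 were present only in firmiensis by this rule and 200 only in N. montana. Between Viviez and N. montana, 187 were present only in Viviez and 464 only in N. montana. Across all 3 plants, 60 transcripts were present in firmiensis and not detected in both others, as were 23 in Viviez and 114 in N. montana. In reverse, 7 transcripts were not detected in firmiensis and present in both others, against 112 for Viviez and 82 for N. montana. The transcript list was assembled from firmiensis, so transcripts that firmiensis does not express are less likely to be listed. That favours few absences in firmiensis, and how far it shaped these numbers was not tested. Comparing single libraries in the same way, between 18 and 135 transcripts (median 47) were present in an individual and not detected in the other individual of the same plant. Between individuals of different plants the numbers ran from 188 to 1045 (median 505.5). The limit of 3 reads over a group corresponds to 0.0219 to 0.025 CPM, so a level below that was not detectable at this depth. These counts changed with the level that defines presence: at 5 CPM in both libraries, 90 were present in firmiensis and not detected in Viviez, and 21 the reverse. Without firmiensis replicate 1 or 2, the 76 transcripts rose to 160 and 189 and the 200 to 347 and 427, and without firmiensis replicate 1 the 188 rose to 298. Without N. montana replicate 1 or 2, the 188 rose to 321 and 339 and the 187 to 299 and 344, and without N. montana replicate 2 the 200 rose to 313. Without Viviez replicate 1 the 464 rose to 776.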

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

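The newer quasi-likelihood fit, the fit without the 20 most abundant transcripts and the presence counts and most abundant transcripts without each library were chosen after seeing the data. No transcript called in a pairwise comparison and called again under an alternative had the opposite direction there (others were not compared), and 59 of 95 recomputed counts of calls stayed within 1.5 times of the reported number. With DESeq2 the counts were 8261 for firmiensis against Viviez, and 2025 higher and 1112 lower in firmiensis than in both others. Over transcripts with at least 1 CPM in every library, so with fewer tested, they were 1971 for firmiensis against Viviez, 5197 for firmiensis against N. montana, 6069 for Viviez against N. montana, and 421 higher and 240 lower than both. With glmTreat against a log2 fold change of 1, a stricter test by construction, they were 1993, 5115, 6737, 492 and 202 in the same order. Deviations of same-numbered libraries correlated at 0.0155, -0.0598 and -0.0374, which shows no strong deviation shared by number. With a single difference per plant, shared handling of same-numbered libraries cannot be excluded. With a replicate block, which takes 1 of the 3 residual degrees of freedom, 2483 transcripts differed between firmiensis and Viviez, 642 were higher and 281 lower in firmiensis than in both, and 7458 and 9485 differed in the comparisons with N. montana.

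Leaving out 1 library gave 668 to 4050 transcripts for firmiensis against Viviez (2369 without firmiensis replicate 1, 929 and 668 without Viviez replicate 1 and 2). It gave 5319 to 7537 for firmiensis against N. montana, lowest without N. montana replicate 1, and 5174 to 12327 for Viviez against N. montana, lowest without Viviez replicate 1. It gave 223 to 818 higher and 112 to 551 lower in firmiensis than in both, each lowest without Viviez replicate 2. Scaling moved the share of higher calls by under 10 percentage points in each comparison. Of 260 recomputed fold changes of named transcripts 247 kept their call, 13 lost it (contig_25404, contig_16363, contig_40138 and contig_1124) and none reversed. The filter of 1 CPM in every library removed the named transcripts and gave no value for them. The tests of gene lists were not run. Leaving out a library leaves its plant with 1 library and the fit with fewer residual degrees of freedom, which alone can lower the calls for that plant. Beyond what is stated, the cause of these changes was not tested.

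Presence in firmiensis without detection in Viviez fell from 347 to 90 transcripts at 5 CPM and 218 at 0 reads, and the reverse from 76 to 21 and 32. Firmiensis without N. montana fell from 188 to 51 and 107, and the reverse from 200 to 35 and 92. Viviez without N. montana fell from 187 to 56 and 98, and the reverse from 464 to 105 and 245. Both settings are stricter by construction. Without 1 library, which loosens the rule, the 6 counts in this order were 422 to 503, 91 to 189 (160 and 189 without firmiensis replicate 1 and 2), 262 to 339 (298 without firmiensis replicate 1, 321 and 339 without N. montana replicate 1 and 2), 276 to 427 (347 and 427 without firmiensis replicate 1 and 2, 313 without N. montana replicate 2), 212 to 344 (299 and 344 without N. montana replicate 1 and 2) and 603 to 776 (776 without Viviez replicate 1). Depth limits absence to 0.0219 to 0.025 CPM over a group.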

Other observations

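Abundant transcripts differed by plant, and those named in this paragraph were singled out after their values were seen. Contig_1579 took 5.3 ± 2.57% of the reads in Viviez leaves (SD, n = 2), against 0.388 ± 0.177% in firmiensis and 0.142 ± 0.0215% in N. montana. The Viviez individuals held 3.482% (exact 95% interval 3.478 to 3.487) and 7.117% (7.11 to 7.124). Its log2 fold change was -3.76 ± 0.73 for firmiensis minus Viviez (SE, edgeR adjusted p = 0.0261) and 5.48 ± 0.79 for Viviez minus N. montana (SE, edgeR adjusted p = 0.00481). Without 1 library these ran from -4.21 to -3.11 and from 4.84 to 5.93, with -3.11 and 4.84 without Viviez replicate 2. The first did not pass the threshold without any 1 of the firmiensis or Viviez libraries (edgeR adjusted p = 0.0522 to 0.0921), and the second passed without each library (edgeR adjusted p = 0.00597 to 0.0225). Contig_32541, the highest on average in N. montana, took 1.608% of reads (exact 95% interval 1.605 to 1.611) in replicate 1 and 0.6892% (0.6873 to 0.6912) in replicate 2, where contig_23505 ranked first with 1.108% (1.106 to 1.11). Contig_32541 stood at 10212 ± 6084 CPM in N. montana, against 10.8 ± 6.46 CPM in Viviez and 33.26 and 1.429 CPM in firmiensis replicates 1 and 2. Its log2 fold change was -9.88 ± 1.84 for Viviez minus N. montana (SE, edgeR adjusted p = 0.0104). Without Viviez replicate 1 and 2 that was -9.37 and -10.66, and the call was lost. For firmiensis minus N. montana the log2 fold change was -9.2 ± 1.79 (SE, edgeR adjusted p = 0.0146), or -8.4 without N. montana replicate 1. It passed without each library (edgeR adjusted p = 0.0119 to 0.0399), at -12.8 without firmiensis replicate 1 and -8.24 without replicate 2. Contig_8694, the most abundant in firmiensis, took 1.33 ± 0.194% of reads there and 0.649 ± 0.0291% in Viviez, a difference that did not pass the threshold (edgeR adjusted p = 0.225). Against N. montana, where it took 0.349 ± 0.199% of reads, it was higher by 2.26 ± 0.57 on the log2 scale (SE, edgeR adjusted p = 0.0299), or by 1.81 to 2.96 without 1 library. This call was lost without firmiensis replicate 1, either Viviez library or N. montana replicate 1 (edgeR adjusted p = 0.0612 to 0.0777).

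The direction of the differences from N. montana was uneven across abundance, taken as the mean CPM of the compared plants with equal weight, in classes chosen after seeing the data. Among transcripts averaging over 100 CPM, 71.6% of those that differed between firmiensis and N. montana were higher in firmiensis, against 51.6% of those under 1 CPM, 47.3% of those from 1 to 10 CPM and 50.7% of those from 10 to 100 CPM. Between Viviez and N. montana the shares higher in Viviez were 67.3% over 100 CPM, and 35.7%, 38.8% and 51.3% in the 3 lower classes. Between firmiensis and Viviez the shares higher in firmiensis were 58% over 100 CPM, and 75.7%, 69.1% and 58.3%. Of the 1080 transcripts that differed in all 3 comparisons, 356 ran from N. montana through firmiensis down to Viviez and 236 from firmiensis through N. montana down to Viviez. A further 200 ran from Viviez through firmiensis down to N. montana, 133 from firmiensis through Viviez down to N. montana, and 80 and 75 had firmiensis lowest with N. montana or Viviez on top.

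Viviez leaves had more transcripts lower than higher against each other plant: 66.9% of the differences from firmiensis were higher in firmiensis, and 44% of those from N. montana were higher in Viviez. Against N. montana this held only for weakly read transcripts. There 51.3% were higher in Viviez from 10 to 100 CPM and 67.3% over 100 CPM, and 48.4% over transcripts with 1 CPM in every library. The tests of abundant transcripts and of read matching were chosen after this was seen. Abundant transcripts taking reads from the rest were examined for the comparison with firmiensis. The 20 most abundant held at most 15.8% of the reads of a Viviez library, a log2 shift of at most 0.25. With every value moved by that shift against the pattern, 65.1% of the calls still at least 2-fold were higher in firmiensis. The smallest called difference was 0.72 on the log2 scale, so this shift could reverse no call and its outcome decides nothing. A refit without the 20 transcripts most abundant over all libraries gave 66.7%, which argues against those 20 as the cause. Without the Viviez library with its own run label number the share was 68.4%, which argues against that library as the only source of the pattern against firmiensis. That fit rests on 1 remaining Viviez library. The share was 73.6% with the library of the other label number left out instead, so a contribution of the labelled library stays open. Poorer matching of reads to a firmiensis reference cannot be told apart: 51.1% of the differences from N. montana, another species, were higher in firmiensis (50.9 to 55.9% without 1 library, against 65.5 to 73.6% for Viviez), but over 100 CPM the order turned, with 71.6% for N. montana and 58% for Viviez, and scaling would absorb a general loss. Sequence divergence was not measured, so genes that Viviez lost or changed, its site and soil, and a lower activity of the same genes all stay open as untested hypotheses.

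The 1782 transcripts that set firmiensis apart from both other plants may reflect the hyperaccumulator, its site, its sampling month or the firmiensis reference. Poorer matching of the other plants' reads to that reference would favour the higher direction, which held 1245 of them, and was not tested here. Shared firmiensis libraries alone are argued against, in a test chosen after this was seen: beyond the 0.632 that the spread between the firmiensis individuals gives, 1.37 of the covariance of both differences was left, though part of the overlap may still come from them. The firmiensis leaves were collected in July and all others in June, and the month cannot be told apart from the plant for any of these transcripts. Viviez, collected in June, was set apart by more transcripts, 2746, but that count does not measure an effect of July in firmiensis. Large differences also arose within June, between Viviez and N. montana, at a root mean square log2 difference of 2.26 to 2.33. July coincides with firmiensis, so the size of any month effect there stays open. No value here ties the 1782 to nickel, and the biological explanation was not tested.

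Reads divided between near-identical transcripts of 1 locus could make neighbouring contigs move in opposite directions, if contig numbers follow loci. Among 2766 pairs of consecutive numbers that both differed between firmiensis and N. montana, 46.1% went in opposite directions, below the 48.1 to 51.8% of random pairs. The log2 fold changes of consecutive numbers correlated at only 0.0355 across pairs, which are not independent, so the numbers carry little information on loci. They also followed abundance (Spearman -0.689 with mean CPM across transcripts), on which direction depends, so random pairs are not a matched baseline, and divided reads cannot be told apart from real differences this way.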
